A study of Mus musculus with 19 samples.

How the data were processed

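Poly(A) RNA sequencing libraries were made from mouse embryonic kidney cells of the CFW strain, with a stranded mRNA library kit from Kapa, per the labels' protocols. RNA was isolated with the RecoverAll kit, made for fixed material, and with the RNeasy Micro kit. The labels do not say which library had which kit. TopHat2, an aligner, Partek, an analysis suite, and the mouse genome build mm10 are named, without versions, roles or order, per the submitters' processing notes. The gene annotation, and whether reads were counted by strand, are not given in the sources used here.

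The authors deposited a table of 15 libraries from embryonic day 16.5 (E16.5) and a table of 4 libraries from day 14.5 (E14.5), with 1 value per gene and library. The deposited values behave as RPKM (reads per kilobase of gene model, scaled by library depth), although the tables are titled TPM. Columns of TPM have equal sums, whereas these sums ran from 339454 to 429529 in the E16.5 table (coefficient of variation 7.99%) and from 342196 to 453324 in the E14.5 table (13.8%). Multiplied by exonic length in kilobases, the sums ran from 949196 to 1021410 (1.91%) and from 1069420 to 1108110 (1.56%). The tests had been designed for TPM; the test for RPKM is the same, and values rescaled to TPM were added as an alternative. The 2 tables were normalised separately, so tests were made within a table only.

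Lengths and positions came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. It held 96.0% of the names of the E16.5 table (20164 lines) and 96.2% of those of the E14.5 table (24454 lines). In each of the tables, 27 names had been turned into dates, and these are not reported by name. Lines of the same name were summed. Depth was estimated from low values, which in RPKM are multiples of what 1 read is worth. Of the low values, 43.0% to 58.1% per library lay within 0.05 reads of a whole number. By chance 10% would for a value of 1 read fixed beforehand. That value was instead chosen per library to make this share and the share of single reads large, so 10% is not its baseline. The estimated read numbers are approximate. Counts could not be recovered for nearly all genes, and no count model was used.

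Values were compared as log2(value + 1) with limma 3.58.1 (linear models with moderated variances, eBayes with an intensity trend, two-sided) in R 4.3.3. The R package data.table, version 1.17.8, read the tables, and depth, positions and figures were computed with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Genes with a value of at least 1 in at least 3 libraries (E16.5, 12817 genes) or at least 2 libraries (E14.5, 12383 genes) were tested. All 15 libraries of the E16.5 table entered 1 fit of 5 group means with 10 residual degrees of freedom. The E14.5 fit had 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with limma's test throughout. Every adjusted p below is from limma's moderated test or, for gene lists, from limma's camera.

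The groups, the tests, the 22 gene lists and the rule for naming genes were chosen before the data were examined. Six2 and Foxd1 are named in each main comparison. Also named are the 8 genes with the largest change in each direction (4 in the other comparisons) among called genes with a mean of at least 5 in the higher group and no overlap between groups, leaving out predicted genes. From each list up to 4 called members with the largest change are named, or the 1 with the largest where none was called. Some genes that meet these rules are not reported here. Any other gene is said to have been chosen after its values were seen. The lists were nephron progenitor, early differentiating nephron, podocyte, tubule, ureteric epithelium, cortical stromal progenitor, interstitial matrix, mural, endothelial, leukocyte, erythroid, neural and glial, cell cycle, immediate early and heat shock, FGF feedback targets, Wnt targets, BMP targets, retinoid pathway, hedgehog targets and receptors, posterior Hox, replication-dependent histones and cytoplasmic ribosomal proteins. Some genes stand in more than 1 list, such as Hoxa11, Aldh1a2 and Rarb. Lists were tested against the other genes with camera at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone.

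Replicate numbers in the labels are shared across groups. Deviations from the group means correlated, across genes, between same-numbered SIX2+ and SIX2− libraries (r = 0.64, 0.28 and 0.68), GFP+ and GFP− libraries (0.45, 0.44 and 0.39) and SIX2− and unsorted libraries (0.42, 0.19 and 0.50), so these numbers were taken to pair the samples. They did not for SIX2+ and unsorted libraries (0.28, 0.06 and 0.30) or for SIX2+ and GFP+ libraries (0.40, −0.02 and 0.58). The main design had no block, and a fit with the replicate number as a block was an alternative. The block was set separately for antibody and GFP libraries. For SIX2+ against GFP+ cells that fit therefore compared fitted levels at replicate 1 only, and is no blocked test of their difference. The other alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5, quantile normalisation, median-of-ratios scaling, no trend, library weights, only the groups compared, and each replicate left out. Lists were also tested with the rotation test fry.

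Each model was tested on simulated values with 200 genes changed. Of genes changed by 1, 2 and 4 on the log2 scale, 67.2%, 85.1% and 97.0% were recovered for SIX2+ against SIX2− cells, and 55.2%, 88.1% and 93.9% for GFP+ against GFP− cells. For Foxd1Tdt+ against Foxd1Tdt− cells the shares were 4.48%, 49.3% and 80.3%. Unchanged genes that were called numbered 8, 11 and 2 in the same order of comparisons. The simulated noise was independent between libraries, unlike that of same-numbered libraries, and fewer genes changed than were called in the data. The shares therefore hold for that setting only. Replicates were checked for duplicates: no pair had identical values, and the lowest mean chi-square per gene of a pair, on estimated reads, was 27.4.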

Results

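Gene expression was measured by RNA sequencing in 19 libraries of cells from mouse embryonic kidneys, in 7 groups. Nephron progenitors, which express the transcription factor SIX2, were obtained in separate ways at E16.5. In one, nephrogenic zone cells (NZC, from the outer rim where nephrons form) were stained for SIX2 and sorted into SIX2+ and SIX2− cells, with unsorted NZC beside them (n = 3 libraries each, titled MARIS, a method for RNA from cells sorted on an intracellular protein). In the other, GFP+ and GFP− cells were sorted from kidneys carrying Six2TGC, an allele with GFP under control of Six2 (n = 3 each). Stromal progenitors were represented at E14.5 by Tdt+ and Tdt− cells of Foxd1Cre;Tdt kidneys, in which cells with a history of Foxd1 expression carry a red reporter (n = 2 each). The study set nephron progenitors against stromal progenitors. The labels do not say that libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

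Depth, estimated in units of 1e+06 reads, was 27.3, 45.7 and 43.3 in the SIX2+ libraries, 26.4, 43.2 and 40.4 in SIX2−, 42.5, 39.0 and 32.2 in GFP+ and 36.0, 44.4 and 26.2 in GFP− libraries. It was 9.47 and 8.43 in Tdt+ libraries and 30.5 and 26.4 in Tdt− libraries. In unsorted NZC it was 34.4, 3.10 and 38.0. NZC library 2 stood apart in more than depth: its median log2 value of replication-dependent histone genes, whose transcripts lack poly(A), was 7.81, against 0.86 to 2.14 in the other 14 libraries of its table. Its Rn45s, ribosomal RNA, was at 762, against 2.12 to 32.5 in those 14 libraries, and its Malat1, a nuclear RNA, at 683, against 27.0 to 134. In the E14.5 table Rn45s was at 2716 and 545 in Tdt− libraries 1 and 2 and at 1928 and 361 in Tdt+ libraries 1 and 2, so there it differed more between replicates than between groups.

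Six2 and Foxd1 were examined first, as a check of the labels. Six2 (ENSMUSG00000024134.11, mm10 chromosome 17, 85684277 to 85688274, minus strand) had 351 ± 92.6 RPKM in SIX2+ cells and 19.6 ± 23.6 in SIX2− cells (mean ± SD, n = 3). The values were 335 ± 20.4 in GFP+ and 7.45 ± 8.08 in GFP− cells, 99.9 ± 57.7 in unsorted NZC, 1.39 ± 1.05 in Tdt+ and 107 ± 14.7 in Tdt− cells (n = 2). In both negative E16.5 fractions library 3 held most of the Six2, at 10.2% of the matched SIX2+ and 4.85% of the matched GFP+ level, against 0.828% to 2.58% in the other pairs. Foxd1 (ENSMUSG00000078302.5, chromosome 13, 98354242 to 98359305, plus strand) had 153 ± 72.9 in Tdt+ and 27.5 ± 3.34 in Tdt− cells (n = 2). It was also present in SIX2+ cells at 22.9 ± 7.32 and in GFP+ cells at 36.0 ± 7.91, against 72.7 ± 26.8 in SIX2− and 78.7 ± 21.5 in GFP− cells (n = 3).

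**Figure D1:**
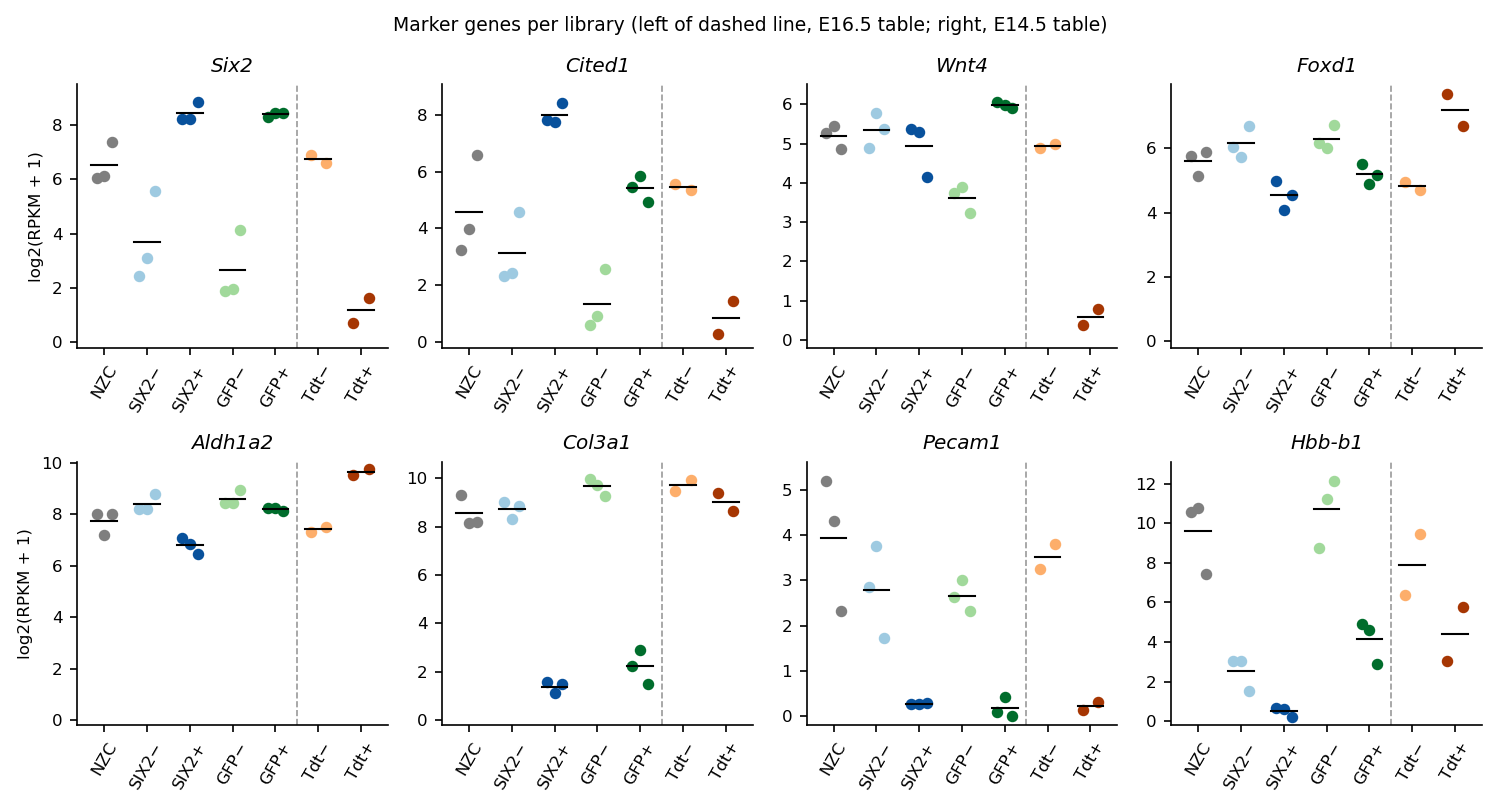
Values of 8 marker genes as log2(RPKM + 1) in each library (points) with group means (lines), for the 5 groups at E16.5 and, right of the dashed line, the 2 groups at E14.5, which were normalised separately. Six2 was high in SIX2+ and GFP+ cells, and Col3a1 was low in both while it stayed high in Tdt+ cells.

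The comparison of SIX2+ with SIX2− cells asked which genes mark nephron progenitors within the nephrogenic zone. Genes known from the cap mesenchyme, the progenitor population around the ureteric tips, were among those that rose most in SIX2+ cells. Beside Six2 (log2 fold change 4.72 ± 0.70 SE, adjusted p = 0.000171), Cited1, a transcriptional coactivator of the least differentiated progenitors, rose by 4.87 ± 0.77 (adjusted p = 0.000291). It had 259 ± 69.5 RPKM in SIX2+ and 10.5 ± 10.8 in SIX2− cells. Crym, a thyroid hormone binding protein, rose by 4.68 ± 0.35, Eya1, a SIX2 partner, by 3.99 ± 0.42, and Spock2, Ocm, Traf1 and Nell1 by 3.94, 3.89, 3.82 and 3.30. Genes of the stroma were lowest relative to SIX2− cells. The fibrillar collagen gene Col3a1 had 1.65 ± 0.416 against 429 ± 102 RPKM (−7.33 ± 0.35, adjusted p = 5.01e-09). Col1a2 followed at −6.67 ± 0.29, the proenkephalin gene Penk at −6.29 ± 0.35, then Bgn at −5.84, Ecm1 at −5.63, Col1a1 at −5.50 and Postn at −5.46. Foxd1 fell by 1.61 ± 0.30 (adjusted p = 0.000982). Of 12817 genes tested, 3109 were called, 1073 higher and 2036 lower, and 397 and 1311 of these differed by at least 1 on the log2 scale. The split depended on scaling, with 1578 higher and 1574 lower after quantile normalisation, and with library weights 7044 genes were called (3408 and 3636). It was 666 and 1611 without SIX2− library 1, 696 and 1631 with replicates 1 and 2 only, 1737 and 2482 without NZC library 2 in the fit, 1697 and 2529 with only the groups compared and 806 and 1271 with values of at least 5.

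Among the nephron lists, 21 of 23 progenitor genes rose in SIX2+ cells and none fell (22 adjusted over the list alone, median 2.44, camera adjusted p = 6.17e-16, adjusted p = 0.0628 with an estimated correlation). Early differentiating nephron genes went the other way: 2 of 18 rose and 10 fell (2 and 12 over the list alone, median −1.56, adjusted p = 8.42e-06, adjusted p = 0.203 with an estimated correlation). The Wnt inhibitor Dkk1 fell (−4.86 ± 0.17), as did the transcription factors Osr2 (−3.62) and Pou3f3 (−2.82). The chemokine receptor Cxcr4 (2.10 ± 0.28) and the cadherin Cdh4 (0.79 ± 0.25) rose. Wnt4, which drives the transition of progenitors to epithelium, was at 31.9 ± 13.1 in SIX2+ and 40.9 ± 12.7 in SIX2− cells and was not called (−0.40 ± 0.30, adjusted p = 0.402; 0.00 with replicates 1 and 2 only), and Pax8 was at 38.0 and 50.1 (adjusted p = 0.293). Cxcr4, Cdh4, Wnt4 and Pax8 were chosen after their values were seen. Podocyte genes fell in 7 of 12 cases (1 risen and 9 fallen over the list alone, adjusted p = 0.000734, adjusted p = 0.357 with an estimated correlation), among them Podxl (−3.39) and Synpo (−2.00). Tubule genes fell in 9 of 11 (10 over the list alone, adjusted p = 9.78e-07, adjusted p = 0.205 with an estimated correlation), among them Pdzk1 (−3.38), Hnf4a (−3.08) and Slc34a1 (−2.62). Of 9 ureteric genes 1 rose and 6 fell (1 and 6 over the list alone, adjusted p = 0.000949, adjusted p = 0.101 with an estimated correlation), with Wnt11 at −2.88, Gata3 at −2.62 and Calb1 at −2.57. Cdh4 lost its call with replicates as a block (adjusted p = 0.0528) and in TPM (0.0687), and without SIX2− library 1 (0.155) or 3 (0.0604) or SIX2+ library 1 (0.0737), 2 (0.0876) or 3 (0.0610), and with replicates 1 and 2 only (0.153). Pax8 was called lower with library weights (0.00198).

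Many stromal, vascular and leukocyte genes were lower in SIX2+ than in SIX2− cells. Of 15 cortical stromal genes 14 fell in SIX2+ cells (1 and 14 over the list alone, median −2.00, adjusted p = 3.03e-12, and adjusted p = 0.0486 with an estimated correlation), including Smoc2 (−4.54), the guidance factor Ntn1 (−4.22) and Fibin (−4.11). Of 15 interstitial matrix genes 14 fell and Tnc rose (1.22 ± 0.24), with a median of −4.52 (1 and 14 over the list alone, adjusted p = 2.54e-15, adjusted p = 0.0628 with an estimated correlation). Of 13 mural genes 10 fell and Des, an intermediate filament gene, rose (1.44 ± 0.24; 1 and 11 over the list alone, adjusted p = 2.83e-07, adjusted p = 0.101 with an estimated correlation). Pdgfrb, a pericyte receptor, had 1.20 ± 0.154 against 65.1 ± 3.95 RPKM, and Rgs5, Acta2 and Kcnj8 were at −4.32, −4.21 and −4.13. Tnc and Des were named after their values were seen. Endothelial genes fell in 13 of 15 (15 over the list alone, adjusted p = 1.82e-07, adjusted p = 0.273 with an estimated correlation), led by Emcn (−4.29), Eng (−4.01), Cldn5 (−3.23) and Cdh5 (−3.02). Leukocyte genes fell in 12 of 13 (12 over the list alone, adjusted p = 4.76e-10, adjusted p = 0.0580 with an estimated correlation), led by Tyrobp (−3.57), C1qb (−3.50), Lyz2 (−3.48) and C1qc (−3.23). None of 10 erythroid genes was called (none over the list alone, median −1.09, camera adjusted p = 0.319, largest Hbb-b1, −2.03 ± 0.91, adjusted p = 0.129). Hbb-b1 was called lower with only the groups compared in the fit (adjusted p = 0.00594), with a pseudocount of 0.1 (0.0225), in TPM (0.0464), with library weights (0.00116) and with replicates 1 and 2 only (0.0294). Globins made up 0.00157% to 0.00592% of the SIX2− values, against 0.127% to 1.31% in unsorted NZC.

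Pathway lists were mixed. Posterior Hox genes, which pattern the caudal body, rose in 10 of 13 cases (11 over the list alone, median 0.95, adjusted p = 9.83e-07, and adjusted p = 0.0486 with an estimated correlation), with Hoxd12 at 2.70 ± 0.30, Hoxb9 at 1.96 ± 0.30, Hoxa11 at 1.10 and Hoxa10 at 1.07. Retinoid pathway genes fell in 6 of 10 (7 over the list alone, adjusted p = 0.000705, adjusted p = 0.101 with an estimated correlation): Crabp1 (−3.37 ± 0.14), Dhrs3 (−1.86), Aldh1a2, which makes retinoic acid (−1.60 ± 0.24), and Rarb (−1.35). Of 10 FGF feedback targets Etv4 (1.54), Il17rd (1.05) and Etv1 (1.03) rose and 2 fell, among them Spry4 at −0.59 (4 and 2 over the list alone, median −0.04, mean 0.24 and test upward, adjusted p = 0.583). Of 9 Wnt targets 1 rose and 4 fell, Lef1 (−2.33), Apcdd1 (−2.09), Nkd1 (−1.08) and Lgr5 (−0.90; 1 and 4 over the list alone, adjusted p = 0.119). Of 8 hedgehog genes Gas1 rose (1.80) and Gli1 (−1.70), Gli2 (−1.58) and Boc (−1.48) fell (1 and 4 over the list alone, adjusted p = 0.119). Of 7 BMP targets Bambi fell (−0.94; 1 over the list alone, adjusted p = 0.474). Of 5 neural genes 2 rose, among them Elavl4 (2.36; 2 over the list alone, median −0.29, mean −0.04 and test upward, adjusted p = 0.552). Of 18 cell cycle genes Cdk1 fell (−0.43; none over the list alone, adjusted p = 0.476), and of 20 immediate early genes Atf3 (−2.25) and Ier3 (−1.18) fell (2 over the list alone, adjusted p = 0.626). Of 52 histone genes Hist3h2ba (1.59) and Hist2h2be (0.75) rose (1 over the list alone, adjusted p = 0.386), and none of 81 ribosomal protein genes was called (none over the list alone, adjusted p = 0.119, largest Rpl22, 0.34, adjusted p = 0.219, but 0.0478 after quantile normalisation). Atf3 lost its call without SIX2− library 1 (adjusted p = 0.0552) or 3 (0.0546) or SIX2+ library 1 (0.0758) or 2 (0.0701), and Ier3 without SIX2+ library 1 (0.0534) or 2 (0.0536) or SIX2− library 3 (0.0541). Etv4 lost it without SIX2− library 1 (0.146) or 2 (0.0803) or SIX2+ library 1 (0.0655), 2 (0.0581) or 3 (0.101), and Etv1 without SIX2− library 1 (0.0529) or SIX2+ library 2 (0.0635). Spry4 lost it without SIX2+ library 1 (0.0964) or SIX2− library 2 (0.0726). Cdk1 lost it without SIX2− library 1 (0.0792) or 2 (0.192) or SIX2+ library 1 (0.117), 2 (0.0847) or 3 (0.0796), and Hist2h2be without any of the 6 libraries (0.0718 to 0.155). Lgr5 lost its call after quantile normalisation (0.0671), Cdk1 with no trend (0.0539) and Etv4 with no filter (0.0610). Hist2h2be lost it with a pseudocount of 0.1 (0.0601), with no filter (0.0726) and in TPM (0.0785). With replicates 1 and 2 only calls were lost by Cdk1 (0.0647), Ier3 (0.0683), Etv1 (0.0677), Spry4 (0.124), Hist3h2ba (0.103) and Hist2h2be (0.0709).

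The comparison of GFP+ with GFP− cells asked the same question with a reporter allele in place of an antibody. Six2 rose by 5.73 ± 0.70 (adjusted p = 2.15e-05), Crym by 5.23 ± 0.35 (284 ± 78.2 against 6.55 ± 2.01 RPKM), Eya1 by 4.57 ± 0.42, Nell1 by 4.40 ± 0.17, Spock2 by 4.38, the cartilage collagen gene Col2a1 by 4.23 and the homeobox gene Uncx by 4.17. Six3, a neighbour of Six2 on chromosome 17 (85613608 to 85629302) known from eye and forebrain development, rose by 4.60 ± 0.92 (adjusted p = 0.00151; 44.3 ± 7.12 against 0.875 ± 0.315). Stromal and red cell genes were lowest. Col3a1 had 4.04 ± 2.35 against 820.0 ± 193 RPKM (−7.43 ± 0.35, adjusted p = 2.53e-09), Penk was at −6.52, and the globin genes Hba-a2, Hbb-bs, Hbb-b1, Hba-a1 and Hbb-bt were between −6.69 and −6.33. Globins have near copies that can share reads, so the value of a single globin gene is uncertain. Foxd1 fell by 1.10 ± 0.30 (adjusted p = 0.0112), and lost its call without GFP+ library 2 (adjusted p = 0.0519) or GFP− library 3 (0.0537) and with replicates 1 and 2 only (0.0940). Of 12817 genes 4219 were called, 2035 higher and 2184 lower, and 600 and 1338 of them differed by at least 1. The split was 1394 and 2568 after median-of-ratios scaling and 1397 and 2532 in TPM, and with library weights 7377 genes were called (4026 and 3351). It was 1306 and 1801 with replicates 1 and 2 only, 3014 and 2689 without NZC library 2 in the fit and 1657 and 1414 with values of at least 5.

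Of 23 progenitor genes 19 rose in GFP+ cells (19 over the list alone, median 2.03, adjusted p = 5.06e-11, adjusted p = 0.131 with an estimated correlation). The 18 early nephron genes were divided, with 5 higher and 6 lower (5 and 8 over the list alone, median −0.45, adjusted p = 0.581). Cxcr4 rose by 3.06 ± 0.28, Cdh4 by 2.74 ± 0.25 and Wnt4 by 2.35 ± 0.30 (62.1 ± 3.09 against 11.6 ± 2.78 RPKM), while Dkk1 fell by 3.92 ± 0.17. Pax8, chosen after its values were seen, rose by 1.92 ± 0.22. Podocyte genes fell in 8 of 12 cases and 1 rose (1 and 8 over the list alone, adjusted p = 0.00132, adjusted p = 0.392 with an estimated correlation), with Podxl at −3.75, Synpo at −1.91 and Nphs1 at −1.71. Tubule genes fell in 6 of 11 (7 over the list alone, adjusted p = 0.00386, adjusted p = 0.499 with an estimated correlation), with Pdzk1 at −2.20, Hnf4a at −2.16 and Sostdc1 at −1.64. Of 9 ureteric genes Gata3 (−2.07), Wnt11 (−1.72), Calb1 (−1.62) and 1 other fell and Hoxb7 rose (1.0, 1 and 5 over the list alone, adjusted p = 0.0545, or 0.0494 with replicates as a block). Sostdc1 lost its call without GFP− library 1 (adjusted p = 0.0715) or GFP+ library 3 (0.0535) and after quantile normalisation (0.0512), and with a pseudocount of 5 (0.0863), and Calb1 with replicates 1 and 2 only (0.118).

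Among the lists of other cells, 13 of 15 cortical stromal genes fell (13 over the list alone, median −2.39, adjusted p = 1.31e-12, and adjusted p = 0.0495 with an estimated correlation), with Ntn1 at −5.91 ± 0.38, Smoc2 at −4.52 and Sfrp1 at −4.32. Interstitial matrix genes fell in 14 of 15 and Tnc rose (0.98; 1 and 14 over the list alone, median −5.35, adjusted p = 8.22e-15, adjusted p = 0.0800 with an estimated correlation), with the PDGF receptor gene Pdgfra at −6.26 and Col1a2 at −6.06. Mural genes fell in 11 of 13 and Des rose (2.16; 1 and 11 over the list alone, adjusted p = 1.83e-06, adjusted p = 0.131 with an estimated correlation), with Acta2 at −4.76, Pdgfrb at −4.65, Rgs5 at −4.17 and Myh11 at −4.01. Endothelial genes fell in 10 of 15 (13 over the list alone, adjusted p = 8.24e-06, adjusted p = 0.391 with an estimated correlation), with Eng at −3.56, Emcn at −3.48, Cdh5 at −3.00 and Pecam1 at −2.48. Leukocyte genes fell in 12 of 13 (12 over the list alone, adjusted p = 5.77e-10, adjusted p = 0.0800 with an estimated correlation), with Lyz2 at −4.68, C1qb at −3.57, C1qc at −3.37 and Tyrobp at −3.20. All 10 erythroid genes fell (10 over the list alone, median −6.33, adjusted p = 1.59e-06, adjusted p = 0.236 with an estimated correlation). Globins made up 0.398%, 2.06% and 3.81% of the GFP− values. Pecam1 lost its call with a pseudocount of 5 (adjusted p = 0.0736), and Tnc with replicates 1 and 2 only (0.0736).

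Of the pathway lists, 11 of 13 posterior Hox genes rose (11 over the list alone, median 1.01, adjusted p = 5.57e-05, adjusted p = 0.0800 with an estimated correlation), with Hoxd12 at 3.54 ± 0.30, Hoxb9 at 2.47, Hoxc11 at 1.28 and Hoxc9 at 1.27. Retinoid genes fell in 4 of 10, with Crabp1 at −2.85, Dhrs3 at −2.76, Rarb at −1.66 and Cyp26b1 at −1.59 (5 over the list alone, adjusted p = 0.00108, adjusted p = 0.131 with an estimated correlation). Of 8 hedgehog genes Gli2 (−2.70), Gli1 (−2.40), Boc (−1.64) and 2 others fell and Gas1 rose (1.30; 1 and 5 over the list alone, adjusted p = 0.00342, adjusted p = 0.325 with an estimated correlation). Of 10 FGF targets Etv4 (2.60), Il17rd (2.44) and Etv5 (1.10) rose and 3 fell, among them Spry4 at −0.95 (3 and 3 over the list alone, median −0.15, mean 0.35 and test upward, adjusted p = 0.945). Of 9 Wnt targets 4 rose, with Notum at 1.49 and Sp5 at 1.46, and 3 fell, with Apcdd1 at −2.54 and Lef1 at −1.66 (4 and 3 over the list alone, median 0.02, mean −0.10 and test downward, adjusted p = 0.945). No BMP target of 7 was called (none over the list alone, adjusted p = 0.945, largest Bambi, −0.53, adjusted p = 0.0833, but 0.0338 with replicates as a block, 0.0493 after median-of-ratios scaling, 0.000686 with library weights and 0.0335 without GFP− library 3). Of 5 neural genes 2 rose, among them Elavl4 (1.62), and Stmn2 fell (−2.91; 2 and 2 over the list alone, adjusted p = 0.945). Of 18 cell cycle genes Mcm6 rose (0.51) and Cdk1 fell (−0.46; none over the list alone, adjusted p = 0.573). Immediate early genes fell in 4 of 20, with Atf3 at −2.67, Nr4a1 at −1.96, Ier3 at −1.40 and Zfp36 at −1.25 (4 over the list alone, adjusted p = 0.0565, but 0.00236 with replicates as a block and 0.0293 after quantile normalisation). Of 52 histone genes Hist3h2ba rose (2.20; 1 over the list alone, adjusted p = 0.707), and of 81 ribosomal genes Rpl22 rose (0.52; none over the list alone, median 0.39, adjusted p = 0.000532, adjusted p = 0.815 with an estimated correlation). Mcm6 lost its call without any of the 6 libraries (adjusted p from 0.0655 to 0.110). Cdk1 lost it without GFP+ library 1 (0.0779) or 3 (0.102) or GFP− library 2 (0.0677) or 3 (0.0689), and Notum without GFP+ library 1 (0.0787), 2 (0.0674) or 3 (0.0742) or GFP− library 2 (0.0719) or 3 (0.139). Rpl22 lost it without GFP− library 1 (0.150), 2 (0.0550) or 3 (0.0796) or GFP+ library 1 (0.103) or 2 (0.179). Stmn2 lost it without GFP− library 1 (0.0924) or GFP+ library 3 (0.0508), Zfp36 without GFP+ library 1 (0.108) or GFP− library 3 (0.0990), and with a pseudocount of 5 Cyp26b1 (0.0514) and Stmn2 (0.0551) did. With no filter calls were lost by Mcm6 (0.0531), Notum (0.0622) and Rpl22 (0.0575), after median-of-ratios scaling by Mcm6 (0.0603) and Rpl22 (0.133), in TPM by Mcm6 (0.139) and Notum (0.0590), with a pseudocount of 0.1 by Notum (0.0516), with only the groups compared by Rpl22 (0.0687), and with replicates 1 and 2 only by Stmn2 (0.144), Mcm6 (0.0535), Cdk1 (0.220) and Notum (0.0982). Rarb shares 52.9% of its exonic length with Top2b, Lef1 34.5% with Gm43352, Notum 29.0% with Notumos and Hoxa11 24.8% with Hoxa11os, all on the opposite strand, and Pdzk1 shares 44.9% with Gpr89, so their values are uncertain in every comparison.

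**Figure D2:**
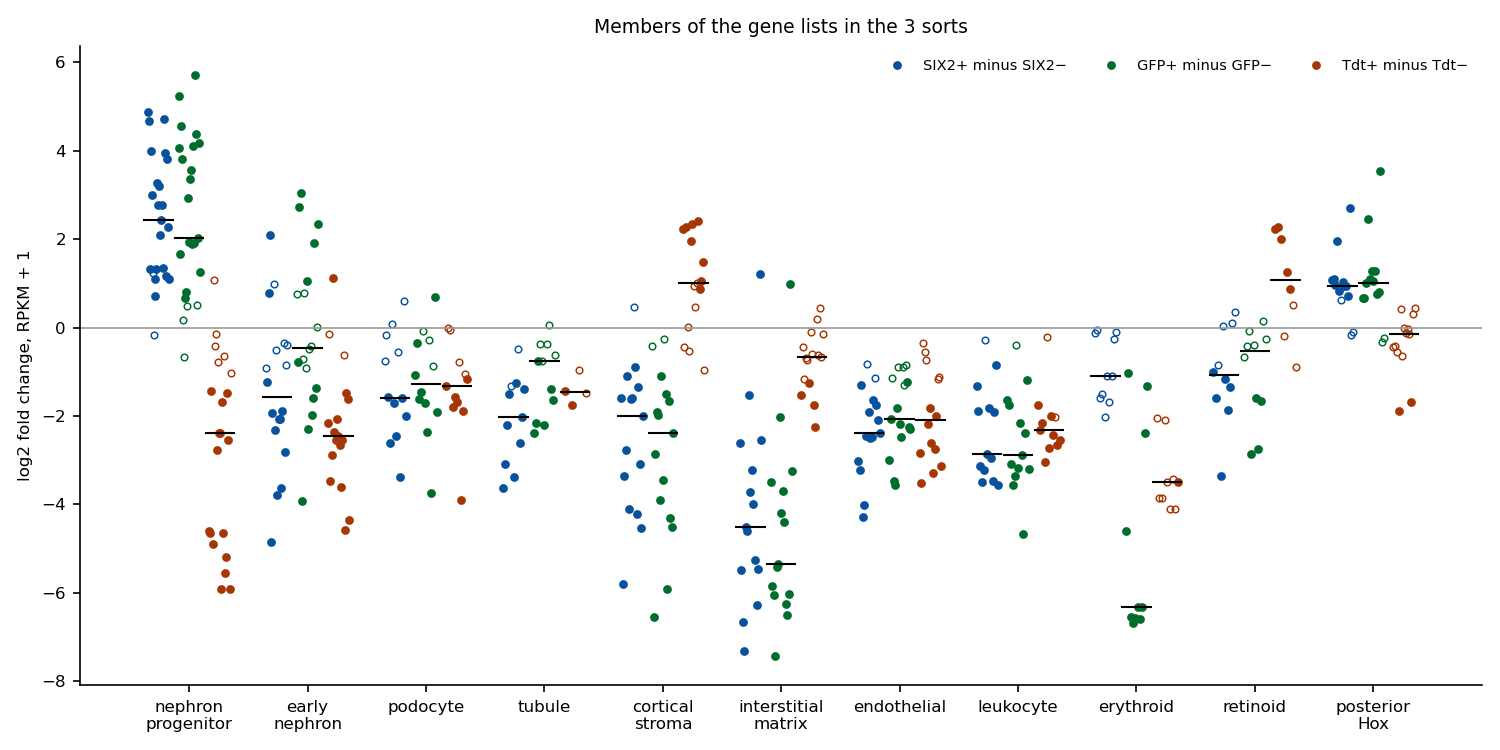
Log2 fold changes, on the RPKM + 1 scale, of the members of 11 gene lists in the sorts by SIX2 antibody, Six2-GFP and Foxd1-Tdt; filled points were called at an adjusted p under 0.05, open points were not, and black lines are list medians. Of the progenitor genes 21 of 23 rose in SIX2+ cells, 19 of 23 rose in GFP+ cells and 15 of 21 fell in Tdt+ cells (adjusted p = 0.0628, adjusted p = 0.131 and adjusted p = 0.237 with an estimated correlation).

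Fold changes of both ways of sorting were then set side by side to ask whether they separated the same genes. Across 12817 genes the log2 fold changes had Pearson's r = 0.913 and Spearman's rho = 0.874, where genes are not independent replicates. Genes higher in both SIX2+ and GFP+ cells numbered 947, where independent lists would share 170.4, and genes lower in both numbered 1678, where independent lists would share 347. No gene was higher in SIX2+ and lower in GFP+ cells, and 7 were lower in SIX2+ and higher in GFP+ cells. Tested by limma as a difference of the differences, enrichment differed for 18 genes (6 higher and 12 lower in the antibody sort), with 703 at an unadjusted p under 0.05.

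Among the called genes named here, Wnt4 differed most in size. Wnt4 had 31.9 RPKM in SIX2+, 40.9 in SIX2−, 62.1 in GFP+ and 11.6 in GFP− cells, a difference of −2.76 ± 0.43 (adjusted p = 0.0266). Pax8, a transcription factor of the nephron epithelium, had 38.0, 50.1, 53.2 and 13.4 (−2.27 ± 0.31, adjusted p = 0.0218). Clu had 16.8, 88.2, 22.6 and 23.6 (−2.20 ± 0.36) and the axon guidance gene Slit1 6.15, 1.96, 23.5 and 0.896 (−2.31 ± 0.40). In the other direction Meis1, a homeobox gene of the stroma, had 16.4, 51.6, 5.34 and 67.7 (1.84 ± 0.21, adjusted p = 0.00544), and Mylk, a kinase gene of smooth muscle, had 4.0, 25.2, 1.09 and 42.9 (1.97 ± 0.29). Itga9 was at 1.45 ± 0.25 and Adamts19 at 1.42 ± 0.21. The early nephron list had a median difference of −1.46, with 3 of 18 genes called (14 over the list alone, adjusted p = 1.09e-21, and adjusted p = 0.0466 with an estimated correlation). The other called gene was Cdh4 (−1.94 ± 0.35), chosen after its values were seen. The erythroid list had a median of 4.72, with no gene called over all genes and 9 of 10 over the list alone (adjusted p = 2.43e-20, adjusted p = 0.0569 with an estimated correlation). The count of 18 fell to 7, 8 and 4 without SIX2+ library 1, 2 or 3, to 6 without SIX2− library 2, to 2 without GFP− library 1 and to 1 without any other GFP library. It rose to 91 without NZC library 2 in the fit, to 138 with only the groups compared, to 38 with a pseudocount of 5 and to 1537 with library weights, and was 11 with no filter, 9 in TPM and 0 with replicates 1 and 2 only (718 at an unadjusted p under 0.05). With replicates as a block 27 genes were called. Mylk (adjusted p = 0.0526), Itga9 (0.0529) and Cdh4 (0.0827) were then not among them. Meis1 kept its call whichever single library was left out. Without any GFP library Pax8 (adjusted p from 0.0503 to 0.104), Wnt4 (0.0660 to 0.104), Mylk (0.0582 to 0.104), Clu (0.0543 to 0.131), Slit1 (0.0691 to 0.161), Itga9 (0.0826 to 0.147), Adamts19 (0.0743 to 0.104) and Cdh4 (0.0833 to 0.183) lost theirs. Wnt4 (0.0958), Slit1 (0.157), Itga9 (0.172), Adamts19 (0.0958) and Cdh4 (0.201) also lost theirs without SIX2− library 2. Without SIX2+ library 3 Mylk (0.0730), Clu (0.131), Slit1 (0.141), Itga9 (0.141) and Cdh4 (0.155) did, without SIX2+ library 1 Adamts19 (0.0613), Slit1 (0.110), Clu (0.10) and Cdh4 (0.110), and without SIX2+ library 2 Itga9 (0.131), Adamts19 (0.0678), Slit1 (0.118), Clu (0.0678) and Cdh4 (0.133). Itga9 was not called without SIX2− library 1 (0.0742), nor Cdh4 without SIX2− library 3 (0.0687). With replicates 1 and 2 only all 9 lost their calls, Meis1 included (0.247). With no filter calls were lost by Itga9 (0.0640), Wnt4 (0.0640), Slit1 (0.0893), Clu (0.0667) and Cdh4 (0.0921), in TPM by Itga9 (0.145), Slit1 (0.145) and Cdh4 (0.147), with no trend by Itga9 (0.0524) and Cdh4 (0.0535), with a pseudocount of 0.1 by Slit1 (0.0750) and Cdh4 (0.0539), and by Slit1 after quantile normalisation (0.113) and median-of-ratios scaling (0.0592). After quantile normalisation the split was 8 higher and 7 lower, after median-of-ratios scaling 7 and 7, and in TPM 4 and 5.

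**Figure D3:**
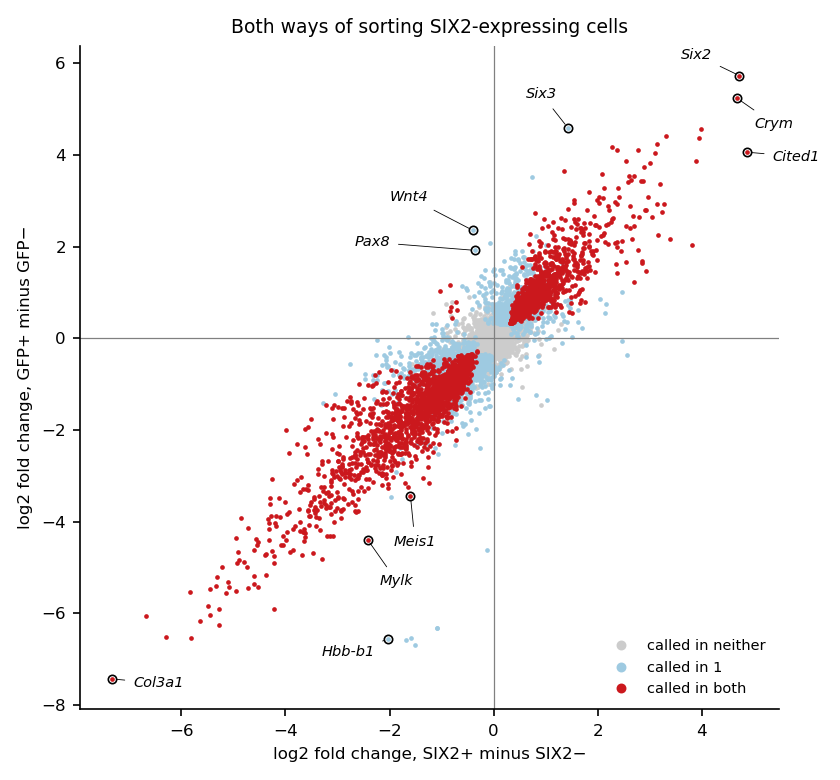
Log2 fold change of each gene between SIX2+ and SIX2− cells (x axis) and between GFP+ and GFP− cells (y axis), on the RPKM + 1 scale, coloured by whether it was called in neither, 1 or both sorts. Across 12817 genes r was 0.913; Wnt4 and Pax8 rose in GFP+ cells and were not called in SIX2+ cells, and globin genes such as Hbb-b1 lie below the other genes.

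SIX2+ and GFP+ cells were also compared directly. Of 9 Wnt targets 3 were lower in SIX2+ cells, Sp5, Lef1 and Axin2, named after their values were seen (4 over the list alone, median −0.73, adjusted p = 0.000143, adjusted p = 0.481 with an estimated correlation). All 3 lost their calls without GFP+ library 1 (adjusted p = 0.0597, 0.180 and 0.227), and Sp5 (0.0681) and Lef1 (0.0636) did with replicates as a block. In this comparison the block fit compared fitted levels at replicate 1 only. Six3 (5.15 ± 8.69 against 44.3 ± 7.12 RPKM, −4.04 ± 0.92, adjusted p = 0.0286), Zbed6 (−3.09 ± 0.34), Nxph1 (−2.92 ± 0.44) and Hbb-b1 (−3.64 ± 0.91) were lowest in SIX2+ cells. Snap91, a clathrin adaptor gene (2.92 ± 0.53), Siglecg (2.74 ± 0.33), Fam189a2 (2.36 ± 0.44) and the growth factor gene Fgf8 (2.15 ± 0.47, adjusted p = 0.0224) were highest. Six2 itself did not separate the fractions (0.04 ± 0.70, adjusted p = 0.996). Zbed6 lies wholly inside the exons of Gm38394 on the same strand, so its value is uncertain. Of the lists, immediate early genes had a median of 0.74 (1 of 20 risen; 1 over the list alone, adjusted p = 0.00453), ribosomal genes 0.29 (none called, adjusted p = 4.6e-05, but 0.326 after quantile normalisation), interstitial matrix −0.37 (1 of 15 fallen; 2 over the list alone, adjusted p = 0.00495) and erythroid −2.16 (1 of 10 fallen; 6 over the list alone, adjusted p = 0.00163). All 4 had adjusted p = 0.998 with an estimated correlation. In all 394 genes were called, 99 higher and 295 lower, or 52 and 287 in TPM. The count was 211, 216 and 229 without SIX2+ library 1, 2 or 3, and 132 and 220 without GFP+ library 1 or 3. It was 985 without NZC library 2 in the fit, 832 with only these 6 libraries, 3091 with library weights and 104 with replicates 1 and 2 only. Six3 lost its call without SIX2+ library 2 (adjusted p = 0.127) or 3 (0.137) or GFP+ library 1 (0.129), 2 (0.0600) or 3 (0.0878), and Fgf8 without SIX2+ library 1 (0.0647), 2 (0.0784) or 3 (0.0940) or GFP+ library 1 (0.0967) or 3 (0.109). Hbb-b1 lost it without SIX2+ library 1 (0.124), 2 (0.115) or 3 (0.146) or GFP+ library 1 (0.222) or 2 (0.10), and Fam189a2 without GFP+ library 1 (0.0531). With replicates as a block, and so at replicate 1 only, Six3 (0.163), Fgf8 (0.0931), Hbb-b1 (0.268) and Snap91 (0.0846) were not called. Neither were the interstitial matrix (0.236) and erythroid (0.642) lists. With no filter calls were lost by Fgf8 (0.0573), Six3 (0.0691), Hbb-b1 (0.0984), Lef1 (0.0662) and Axin2 (0.0578), after quantile normalisation by Fgf8 (0.0515), Hbb-b1 (0.0634) and Lef1 (0.0581), in TPM by Fgf8 (0.0514) and Axin2 (0.0530), with a pseudocount of 0.1 by Fgf8 (0.0542) and Six3 (0.0884) and of 5 by Hbb-b1 (0.258) and Lef1 (0.152), and with replicates 1 and 2 only by Fgf8 (0.0804), Six3 (0.205), Nxph1 (0.0557), Sp5 (0.150), Lef1 (0.298) and Axin2 (0.123).

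Unsorted NZC served as the reference for what each antibody-sorted fraction gained or lost. Unsorted cells hold SIX2+ cells too, yet SIX2+ cells had more genes called against them (4697) than against SIX2− cells (3109). Not all of these calls can therefore be read as gained or lost by sorting. Six2 rose by 1.91 ± 0.70 in SIX2+ cells (adjusted p = 0.0457) but not without NZC library 1 (0.114) or 2 (0.110) or SIX2+ library 1 (0.0819), 2 (0.0765) or 3 (0.130), nor after quantile normalisation (0.0736) or median-of-ratios scaling (0.0655), in TPM (0.0827), with a pseudocount of 0.1 (0.0641), with no filter (0.0890) or with library weights (0.0502). SIX2+ cells exceeded unsorted cells in Cited1 (259 ± 69.5 against 39.2 ± 47.9 RPKM, 3.40 ± 0.77, adjusted p = 0.00428), Traf1 (2.98), Col11a2 (2.66) and Kazald1 (2.66), and had less globin RNA, with Hbb-b1 at −9.10 ± 0.91, Hbb-bs at −8.45, Hba-a2 at −8.23 and Hba-a1 at −8.01. Of 23 progenitor genes 19 rose (21 over the list alone, median 1.43, adjusted p = 2.77e-07, adjusted p = 0.190 with an estimated correlation). All 15 endothelial genes fell (15 over the list alone, adjusted p = 3.07e-09, adjusted p = 0.190 with an estimated correlation), as did 7 of 10 erythroid genes (8 over the list alone, adjusted p = 8.59e-07, adjusted p = 0.190 with an estimated correlation) and all 11 tubule genes (11 over the list alone, adjusted p = 9.55e-08, adjusted p = 0.187 with an estimated correlation). Histone genes had a median of −1.90 with 1 of 52 called, upward (none over the list alone, adjusted p = 0.00122, adjusted p = 0.745 with an estimated correlation), beside the high histone values of NZC library 2. Of 12817 genes 4697 were called, 2320 higher and 2377 lower, but 1580 and 2807 after median-of-ratios scaling and 1281 and 2668 in TPM. With only these 6 libraries in the fit 1879 were called (574 and 1305). The split was 1513 and 1879 without SIX2+ library 1, 1395 and 1965 without SIX2+ library 3 and 1906 and 1529 with values of at least 5. Without NZC library 2 it was 1970 and 2612, with 3759 of these calls shared with the main fit.

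SIX2− cells lay nearer to unsorted cells, with 1424 genes called (661 higher, 763 lower). Progenitor genes fell in 9 of 23 cases (9 over the list alone, median −0.84, adjusted p = 9.17e-08, adjusted p = 0.564 with an estimated correlation), with Six2 at −2.81 ± 0.70 (adjusted p = 0.0237) and, chosen after their values were seen, Crym at −3.02 ± 0.35 and Eya1 at −2.55 ± 0.42. Leukocyte genes rose in 4 of 13 (6 over the list alone, adjusted p = 0.0118, adjusted p = 0.819 with an estimated correlation), among them the adaptor gene Tyrobp (2.21 ± 0.50). The matrix gene Mgp (138 ± 49.8 against 30.2 ± 15.7 RPKM, 2.25 ± 0.41), Snai1 (2.23 ± 0.55) and Rsc1a1 (2.32 ± 0.31) also rose. Rsc1a1 lies wholly inside Ddi2 on the same strand, so its value is uncertain. Globin genes were far lower than in unsorted NZC, with Hbb-b1 at −7.07 ± 0.91, Hbb-bs at −6.77, Hba-a2 at −6.73 and Hba-a1 at −6.41, and 7 of 10 erythroid genes fell (8 over the list alone, adjusted p = 4.74e-10, adjusted p = 0.564 with an estimated correlation). Jag1, a Notch ligand chosen after its values were seen, was at 27.4 ± 9.70 and 27.6 ± 3.66 (−0.05 ± 0.30, adjusted p = 0.921). Histone genes had a median of −2.04 with none called (none over the list alone, adjusted p = 1.82e-08, adjusted p = 0.832 with an estimated correlation). The count moved with the libraries: 2406 without NZC library 1, 2425 without 3, and 400, 364 and 834 without SIX2− library 1, 2 or 3. Without NZC library 2 it was 1166, with 891 of these calls shared with the main fit. It was 2473 with replicates as a block, 2428 with library weights, 280 with replicates 1 and 2 only, 21 with only these 6 libraries in the fit, and 769 in TPM (157 higher, 612 lower), and median-of-ratios scaling gave 546 higher and 982 lower. Calls of Six2, Snai1 and Tyrobp were lost without SIX2− library 1 (adjusted p = 0.0947, 0.0558 and 0.0522) or 2 (0.0986, 0.103 and 0.0694). With only these 6 libraries in the fit Hbb-b1 kept its call, and calls were lost by Six2 (adjusted p = 0.169), Crym (0.0548), Eya1 (0.105), Tyrobp (0.171), Mgp (0.0925), Snai1 (0.205), Rsc1a1 (0.0609), Hbb-bs (0.0541), Hba-a2 (0.0609) and Hba-a1 (0.0609). Snai1 and Tyrobp also lost theirs in TPM (0.0573 and 0.0592) and with replicates 1 and 2 only (0.0911 and 0.0756), and Tyrobp with a pseudocount of 0.1 (0.0849).

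Tdt+ cells of E14.5 kidneys were compared with Tdt− cells to describe stromal progenitors. Foxd1 rose by 2.35 ± 0.34 (adjusted p = 0.00585) and with it Ntn1 (170 ± 41.9 against 31.0 ± 3.73 RPKM, n = 2; 2.40 ± 0.26, adjusted p = 0.00214), the retinoic acid binding protein gene Crabp1 (2.27 ± 0.23), Aldh1a2 (803 ± 99.7 against 170 ± 15.5; 2.23 ± 0.35), Igfbp6 (2.34), C1qtnf2 (2.16) and Vstm2b (2.10). Nephron lineage genes were lowest: Pax2, required for the nephron lineage and the ureteric bud, had 0.409 ± 0.0863 against 84.7 ± 13.2 RPKM (−5.92 ± 0.24, adjusted p = 0.000122). Uncx was at −5.91, Six2 at −5.56 ± 0.33, Spock2 at −5.18, Col2a1 at −4.91, Eya1 at −4.90, Rspo1 at −4.65 and Crym at −4.65. Of 12383 genes 1044 were called, 151 higher and 893 lower, and 127 and 840 of these differed by at least 1. In Tdt+ libraries, which were the least deep of their table, genes of low expression were measured less well. The split was 254 and 504 after quantile normalisation, and 60 and 1064 in TPM, where the median of all genes lay at −0.29. It was 13 and 418 without Tdt− library 1, 9 and 328 without Tdt− library 2, 1278 and 2058 without Tdt+ library 1, 295 and 938 without Tdt+ library 2, 19 and 361 with no filter and 114 and 408 with values of at least 5. Foxd1 lost its call without Tdt− library 1 (adjusted p = 0.0522) or 2 (0.0886), while Ntn1 and Pax2 kept theirs. With no filter Foxd1 (0.0834), Igfbp6 (0.0609) and Aldh1a2 (0.0672) lost theirs.

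The cortical stromal list rose in Tdt+ cells, with 8 of 15 genes called (10 risen and 1 fallen over the list alone, median 1.0, adjusted p = 3.04e-07, adjusted p = 0.395 with an estimated correlation). Retinoid genes rose in 5 of 8 (5 and 1 over the list alone, median 1.07, adjusted p = 0.000184, adjusted p = 0.395 with an estimated correlation), with Crabp2 at 2.01 and Dhrs3 at 1.26 beside Crabp1 and Aldh1a2. Interstitial matrix genes did not: 4 of 15 fell and none rose (4 over the list alone, median −0.66, adjusted p = 0.00391, adjusted p = 0.559 with an estimated correlation), namely the proteoglycan genes Lum (−2.24 ± 0.25) and Dcn (−1.24 ± 0.26), the collagen crosslinking enzyme gene Lox (−1.76 ± 0.26) and Alx1 (−1.52 ± 0.28). Col3a1, chosen after its values were seen, had 662 and 403 RPKM in Tdt+ and 713 and 972 in Tdt− libraries and was not called (−0.69 ± 0.47, adjusted p = 0.428). Penk (−0.63 ± 0.43, adjusted p = 0.428) and Col1a2 (−1.15 ± 0.42, adjusted p = 0.152), chosen likewise, were not called either. Without Tdt+ library 1 Col3a1 (−1.05, adjusted p = 0.0414) and Col1a2 (−1.52, adjusted p = 0.00797) were called lower, and without Tdt+ library 2 Penk was (−1.28, adjusted p = 0.0168). Mural genes fell in 2 of 12, with Des at −1.61 and Mcam at −1.16 (1 risen and 3 fallen over the list alone, adjusted p = 0.0515, but 0.00774 after quantile normalisation). Without Tdt− library 1 or 2, calls were lost by Aldh1a2 (adjusted p = 0.398 and 0.322), Dhrs3 (0.209 and 0.185), Dcn (0.127 and 0.345), Lox (0.0611 and 0.114), Alx1 (0.195 and 0.206), Des (0.185 and 0.0598) and Mcam (0.141 and 0.426), and without library 2 by Crabp2 (0.132). With no filter calls were lost by Dcn (0.10), Lox (0.0655), Alx1 (0.0922), Des (0.0825), Mcam (0.107) and Crabp2 (0.0679). Lum kept its call. Penk turned to 0.03 without Tdt+ library 1.

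Progenitor genes fell in 15 of 21 cases in Tdt+ cells (1 risen and 17 fallen over the list alone, median −2.40, adjusted p = 6.48e-17, adjusted p = 0.237 with an estimated correlation) and early nephron genes in 14 of 17 (15 over the list alone, median −2.46, adjusted p = 3.43e-13, adjusted p = 0.389 with an estimated correlation), with Pax8 at −4.59, Wnt4 at −4.35, Cdh4 at −3.47 and Lhx1 listed at 0 in both Tdt+ libraries against a mean of 11.3 in Tdt−. Dkk1, chosen after its values were seen, was the 1 early nephron gene that rose (1.13 ± 0.25, adjusted p = 0.0324). Podocyte genes fell in 7 of 11 (9 over the list alone, adjusted p = 1.46e-06, adjusted p = 0.395 with an estimated correlation), with Podxl at −3.91 and Ptpro at −1.88. Tubule genes fell in 2 of 4, with Lrp2 at −1.74 and Hnf4a at −1.43 (4 over the list alone, adjusted p = 0.00323, adjusted p = 0.486 with an estimated correlation), and of 4 ureteric genes Calb1 fell (−1.45; 1 over the list alone, adjusted p = 0.559). Endothelial genes fell in 9 of 14 (12 over the list alone, adjusted p = 7.05e-12, adjusted p = 0.395 with an estimated correlation), with Cldn5 at −3.52, Pecam1 at −3.29, Tie1 at −3.14 and Cdh5 at −2.85. Leukocyte genes fell in 9 of 11 (10 over the list alone, adjusted p = 6.38e-08, adjusted p = 0.486 with an estimated correlation), with C1qc at −3.05, Csf1r at −2.73, Mrc1 at −2.65 and Tyrobp listed at 0 in both Tdt+ libraries. Of 9 erythroid genes Hbb-y fell (−3.49; 9 over the list alone, adjusted p = 0.000102, adjusted p = 0.537 with an estimated correlation), and globins made up 0.0915% and 0.699% of the Tdt− values. Without Tdt− library 1 or 2, calls were lost by Dkk1 (adjusted p = 0.332 and 0.280) and Hbb-y (0.0659 and 0.244). Without library 2 Calb1 (0.0865), Lrp2 (0.0668) and Hnf4a (0.142) lost theirs. With no filter calls were lost by C1qc (0.111), Csf1r (0.0995), Mrc1 (0.0971), Tyrobp (0.0876), Cldn5 (0.0540), Lrp2 (0.156), Hnf4a (0.150), Calb1 (0.0847), Hbb-y (0.189) and Dkk1 (0.104). After quantile normalisation Lrp2 (0.158), Hnf4a (0.228) and Calb1 (0.118) lost theirs, with a pseudocount of 5 Lrp2 (0.0643) and Hnf4a (0.0624), with a pseudocount of 0.1 Hbb-y (0.0975) and in TPM Dkk1 (0.0900).

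Of the remaining lists, Wnt targets fell in 2 of 7, Apcdd1 (−1.31) and Notum, listed at 0 in both Tdt+ libraries (4 over the list alone, adjusted p = 0.0014, adjusted p = 0.471 with an estimated correlation). Cell cycle genes rose in 2 of 18, Cdk1 by 1.04 and Birc5 by 0.90 (3 over the list alone, adjusted p = 0.00323, but 0.630 after quantile normalisation, adjusted p = 0.413 with an estimated correlation). Of 10 FGF targets Spry4 rose (1.04) and Il17rd (−3.07) and Etv1 (−1.47) fell (2 and 2 over the list alone, median 0.13, mean −0.14 and test upward, adjusted p = 0.577). Of 7 BMP targets Id4 fell (−2.79; 1 over the list alone, adjusted p = 0.410). Of 8 hedgehog genes Ptch1 fell (−1.51; 1 and 2 over the list alone, adjusted p = 0.780). Of 13 posterior Hox genes Hoxb9 (−1.90) and Hoxd12 (−1.68) fell (2 over the list alone, adjusted p = 0.410). Of 3 neural genes Elavl4 fell (−1.62; 1 over the list alone, adjusted p = 0.513). No immediate early gene of 20 was called (none over the list alone, median 0.44, adjusted p = 0.0515, largest Hspa1a, −1.72, adjusted p = 0.0973, but 0.0181 without Tdt− library 1). Of 34 histone genes Hist1h2bl (−1.72) and Hist1h3h (−1.54) fell (2 over the list alone, adjusted p = 0.368, but 0.0207 after quantile normalisation), and no ribosomal gene of 82 was called (none over the list alone, median 0.66, adjusted p = 1.76e-09, adjusted p = 0.601 with an estimated correlation, largest Rpl35, 1.06, adjusted p = 0.292, but 0.00412 without Tdt+ library 1). The count of 1044 was 431 without Tdt− library 1, 337 without Tdt− library 2 and 3336 without Tdt+ library 1, where the lone library was assumed to vary like the other group. It was 380 with no filter and 522 with values of at least 5. Without Tdt− library 1 or 2, calls were lost by Cdk1 (adjusted p = 0.333 and 0.495), Birc5 (0.380 and 0.426), Spry4 (0.414 and 0.325), Apcdd1 (0.0820 and 0.281), Hoxb9 (0.0747 and 0.0501) and Hist1h3h (0.193 and 0.191). Without library 2 Etv1 (0.110), Id4 (0.0662), Ptch1 (0.334) and Elavl4 (0.0684) lost theirs, and without library 1 Hoxd12 (0.135). Birc5 was also not called with Tdt+ library 2 left out (0.0619), with a pseudocount of 5 (0.0523) or with no trend (0.0658). With no filter calls were lost by Apcdd1 (0.0903), Cdk1 (0.116), Birc5 (0.10), Spry4 (0.0888), Etv1 (0.0834), Id4 (0.0852), Ptch1 (0.141), Hoxd12 (0.114), Elavl4 (0.0654), Hist1h2bl (0.0582) and Hist1h3h (0.174). After quantile normalisation calls were lost by Cdk1 (0.0629), Birc5 (0.0708), Etv1 (0.0559), Hist1h2bl (0.0673) and Hist1h3h (0.109), in TPM by Cdk1 (0.0859), Birc5 (0.149), Spry4 (0.163) and Hist1h3h (0.0683), with a pseudocount of 0.1 by Cdk1 (0.0553), Birc5 (0.0584) and Hist1h3h (0.124), with values of at least 5 by Cdk1 (0.0505) and Birc5 (0.0578) and after median-of-ratios scaling by Cdk1 (0.0514) and Birc5 (0.0531).

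The stromal sort was set against both SIX2 sorts to ask how nephron and stromal progenitors differ, with stage and table differing as well. The negative cells of each sort could include the positive cells of the other. Six2 was at 117 and 96.6 RPKM in Tdt− libraries. Foxd1 was at 51.4 to 103 RPKM in SIX2− and 62.5 to 103 in GFP− libraries. Opposite signs are thus in part built into the design, and independent lists are not a neutral baseline for the overlaps. Genes higher in both SIX2+ and GFP+ cells and lower in Tdt+ cells numbered 251 of 12061 tested in all, where independent lists would share 63.2. In the reverse direction the number was 106 against 18.3. The overlaps are given for the main settings only. With no filter 19 genes were called higher in Tdt+ cells, so overlaps with those genes depend on the settings. No gene was higher in the positive cells of all sorts (10.4 by independent lists), and 153 were lower in all (111). Between GFP and Foxd1 sorts, Pearson's r across genes was −0.197 and Spearman's rho −0.178, with 344 genes higher in GFP+ and lower in Tdt+ cells (138 by independent lists), 115 the other way (23.9), and 189 lower in both (145). Between antibody and Foxd1 sorts r was −0.201 and rho −0.278. Left out, Tdt− library 1 moved these r to −0.0962 and −0.105. Pax2, Six2, Eya1 and Crym were among genes with opposite signs, as were Ntn1 and Crabp1, whereas endothelial genes such as Pecam1 fell in both GFP+ and Tdt+ cells.

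**Figure D4:**
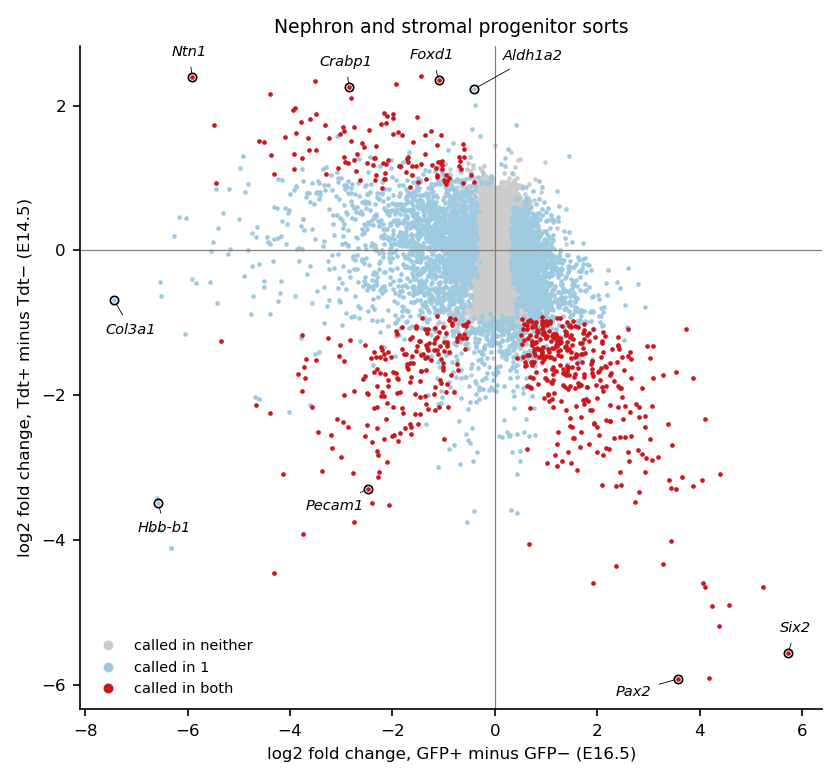
Log2 fold change of each gene between GFP+ and GFP− cells at E16.5 (x axis) and between Tdt+ and Tdt− cells at E14.5 (y axis), on the RPKM + 1 scale, coloured by whether it was called in neither, 1 or both. Six2 and Pax2 lie at the lower right, Foxd1, Ntn1 and Crabp1 at the upper left, and Pecam1 at the lower left; r across 12061 genes was −0.197.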

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

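The tests of explanations in this paragraph and the next were chosen after the results were seen. The results below were singled out because a test of the difference itself found that enrichment in positive cells differed between the antibody sort and the GFP sort. There were 18 such genes. Enrichment in the antibody sort less that in the GFP sort was negative for Wnt4 (−2.76), Slit1 (−2.31), Pax8 (−2.27) and Clu (−2.20), and positive for Mylk (1.97), Meis1 (1.84), Itga9 (1.45) and Adamts19 (1.42). Median differences of the lists that passed were −1.46 for early nephron, −0.92 for tubule, −0.55 for ureteric epithelium, −0.45 for Wnt targets and −0.26 for ribosomal proteins. On the other side they were 4.72 for erythroid genes, 0.62 for hedgehog genes, 0.48 for interstitial matrix, 0.47 for immediate early genes, 0.39 for cortical stroma and 0.14 for leukocytes. Of these only the early nephron list passed with an estimated correlation (adjusted p = 0.0466). The numbers pair the libraries within each sort, and only 10 splits of the 12 libraries keep every pair, too few for a share under 0.05. The real one gave 18 genes (703 at an unadjusted p under 0.05) and the highest other 0 (limma, 100 at an unadjusted p under 0.05), so 1 of 10 gave as many. Of 100 drawn splits, which mostly part the pairs, 2 gave 18 genes or more and 22 gave 703 or more at an unadjusted p under 0.05, the real one included. The highest of these gave 2500 genes (4539 unadjusted). It set SIX2+ with GFP− and GFP+ with SIX2− libraries, so it follows the sorting itself, a structure of the samples.

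The first pattern weighed was that early nephron genes were enriched less by the antibody sort than by the GFP sort. Scaling by the authors is argued against, since the median difference stayed at −1.35 or lower under 4 scalings, and so is depth, since the antibody-sorted libraries had 1.03 times the mean reads of the GFP-sorted ones. If reporter protein outlasted SIX2 in differentiating cells, SIX2+ cells should have had less of the list than GFP+ cells. SIX2− cells should also have had more of it than GFP− cells. The latter was met, with a median of 1.37 (18 of 18 genes). The former was not shown by the list's median of 0.0575 for SIX2+ less GFP+ cells. Still, Wnt4 (−1.04 ± 0.30, adjusted p = 0.0891, but 0.0206 with library weights) and Pax8 (−0.48 ± 0.22, adjusted p = 0.308, but 0.0486 with only the groups compared) were lower in SIX2+ cells. So was Cdh4 (−1.13 ± 0.25, adjusted p = 0.0216). Cdh4 was not called with replicates 1 and 2 only (0.341) or without any of the 6 SIX2+ and GFP+ libraries but GFP+ library 2 (0.0699 to 0.124). With the block, at fitted levels of replicate 1, its adjusted p was 0.0861. These genes were the list members called in the test of the difference between sorts. Being picked that way favours a lower level in SIX2+ cells. Fgf8, also of the list, was called higher in SIX2+ cells, as given above, though not in every fit. The explanation stays open. By median most of the difference lay in the negative fractions, where the list was higher in SIX2− than in GFP− cells by 1.37 (18 of 18 genes), but so were tubule (0.96, 11 of 11), ureteric (0.60, 9 of 9) and ribosomal protein genes (0.56, 81 of 81), while erythroid (−7.40, 0 of 10) and interstitial matrix genes (−0.85, 0 of 15) were lower. Starting material is a candidate explanation that cannot be told apart from method and allele. The labels give nephrogenic zone cells for one sort and cells in developing kidneys for the other, without saying whether those were whole kidneys. Whole kidneys should bring a higher level of tubule genes to GFP− cells, which was not seen. Interstitial matrix genes were higher in GFP− cells, so the lists do not decide the question. Erythroid genes were higher there too, but that gap cannot be read as one of starting tissue. Globins made up 0.127% to 1.31% of the values in unsorted NZC and 0.00157% to 0.00592% in SIX2− cells.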

How the results depend on the processing

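Of the counts and correlations under other settings, 116 stayed within limits and 71 moved. Of the results of gene lists 353 were the same, 77 weaker and 10 stronger. Of those of named genes 4888 were the same, 442 weaker, 28 stronger and 15 turned sign. Rescaling to TPM, leaving out NZC library 2, and using replicates 1 and 2 only were chosen after seeing the data. Unless its construction shows it (fewer samples or genes), the cause was not tested. Depth limits the Tdt+ libraries and NZC library 2 most.

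Counts of called genes were, for SIX2+ against SIX2−, 7044 with library weights (3109 without), and 2277 to 2813 with a library left out. For GFP+ against GFP− they were 7377 with weights and 3100 to 3619. For Tdt+ against Tdt− they were 380 with no filter, 522 with values of at least 5, and 337 to 3336. For SIX2+ against NZC they were 1879 with only the groups compared and 3360 to 5574. For SIX2− against NZC they were 2428 with weights, 769 in TPM, 21 with only the groups compared, 280 with replicates 1 and 2, and 364 to 2425. For the difference between sorts they were 38 with a pseudocount of 5, 11 with no filter, 1537 with weights, 9 in TPM, 138 with only the groups compared, 91 without NZC library 2 in the fit, 0 with replicates 1 and 2 (limma, 718 at an unadjusted p under 0.05), and 1 to 25. For SIX2+ against GFP+ they were 3091 with weights, 832 with only the groups compared, 985 without NZC library 2, 104 with replicates 1 and 2, and 132 to 466.

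With replicates as a block the counts were 2473 for SIX2− against NZC, 3719 for SIX2+ against SIX2−, 5033 for GFP+ against GFP− and 27 for the difference between sorts. Where numbers did not pair the samples, they were 5640 for SIX2+ against NZC (5 of 6 libraries correlated best with their own number) and 412 for SIX2+ against GFP+ (4 of 6). The count of 412 is for fitted levels at replicate 1 only. For Tdt+ against Tdt− the count was 2307, where 4 of 4 libraries correlated best with their own number (r = 0.40). With 2 libraries per group the deviations mirror each other, so this r is 1 value for both pairs. In that last comparison the block gave an adjusted p of 0.000837 for the mural and 0.0103 for the immediate early list, and 4.1e-05 for Hspa1a. The block changed no call that is not named here or beside its result.

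The correlation of antibody and GFP folds was 0.931 with a pseudocount of 0.1, 0.898 with 5, 0.925 with values of at least 5, 0.902 after quantile normalisation, 0.874 by rank and 0.925 over called genes, and 0.898 to 0.923 with a library left out. That of GFP and Foxd1 folds was −0.127 with a pseudocount of 0.1, −0.312 over called genes, and −0.290 to −0.0962. That of antibody and Foxd1 folds was −0.0890 with a pseudocount of 0.1, −0.278 with 5, −0.275 with values of at least 5, −0.124 in TPM, −0.278 by rank, −0.372 over called genes, and −0.287 to −0.105.

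Values that turned sign had not been called. Wnt4 in SIX2+ against SIX2− was 0.00267 with replicates 1 and 2 only. Jag1 in SIX2− against NZC was 0.44 with weights, 0.10 with replicates 1 and 2, and −0.31 to 0.14 with a library left out (0.05 without NZC library 2, 0.02 and 0.14 without SIX2− library 1 or 3). Six2 in SIX2+ against GFP+ was −0.13 after quantile normalisation, −0.00146 after median-of-ratios scaling, −0.0647 with weights, −0.0853 in TPM, −0.14 with replicates 1 and 2, and −0.17 to 0.15 with a library left out (−0.17 and −0.01 without SIX2+ library 3 or GFP+ library 1). With replicates as a block its difference between fitted levels at replicate 1 was −0.16. Penk in Tdt+ against Tdt− was −1.28 to 0.0269 with a library left out (0.0269 without Tdt+ library 1).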

Other observations

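Genes in this paragraph were chosen after their values were seen. SIX2+ and GFP+ cells had like levels of Six2 and differed in single genes, given here as values without a test of them as a group. Meox2 (22.2 ± 4.78 against 4.90 ± 0.764 RPKM, 1.97 ± 0.42, adjusted p = 0.0194) and Tmem100 (1.45 ± 0.31) were higher in SIX2+ cells. Cited1 had 259 ± 69.5 against 43.1 ± 13.7 RPKM but was not called (2.58 ± 0.77, adjusted p = 0.0991), though it was with only the groups compared in the fit (0.00172), with a pseudocount of 5 (0.0406), with library weights (0.00312) and with replicates 1 and 2 only (0.0255). Meis1 was higher in SIX2+ cells (1.45 ± 0.15). The Wnt targets Sp5 (−1.09 ± 0.21), Lef1 (−0.80) and Axin2 (−0.73), the hedgehog receptor gene Ptch1 (−1.70 ± 0.32) and Aldh1a2 (112 ± 24.0 against 292 ± 14.8 RPKM, −1.40 ± 0.24) were lower. With the replicate number as a block Meox2 (adjusted p = 0.164), Tmem100 (0.181), Aldh1a2 (0.0879), Sp5 (0.0681) and Lef1 (0.0636) were not called. The numbers did not pair these groups by the rule used, and the block fit compared fitted levels at replicate 1 only. Without GFP+ library 1 calls were lost by Meox2 (adjusted p = 0.0715), Tmem100 (0.102), Sp5 (0.0597), Lef1 (0.180), Axin2 (0.227) and Ptch1 (0.0679), and without GFP+ library 3 by Meox2 (0.0873), Tmem100 (0.0912), Lef1 (0.111), Axin2 (0.104) and Ptch1 (0.0511). SIX2+ libraries mattered too: without library 1 calls were lost by Meox2 (0.0735), Lef1 (0.0845), Axin2 (0.120) and Ptch1 (0.0514), without library 2 by Meox2 (0.0881), Tmem100 (0.0941) and Axin2 (0.135), and without library 3 by Lef1 (0.167) and Axin2 (0.112). Lef1 was also not called without GFP+ library 2 (0.0704). Meis1 and Aldh1a2 kept their calls whichever single library was left out. In TPM Meox2 (0.0518) and Tmem100 (0.0512) lost theirs, and with replicates 1 and 2 only Tmem100 (0.150), Aldh1a2 (0.0609) and Ptch1 (0.0557) did.

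Against unsorted cells, SIX2− cells had no stromal list that passed: of 15 cortical stromal genes 3 rose and 1 fell (5 and 1 over the list alone, camera adjusted p = 0.119), of 13 mural genes 2 rose (3 over the list alone, adjusted p = 0.112), and no interstitial matrix gene of 15 was called (adjusted p = 0.819). Of single genes chosen after their values were seen, Crabp1 (66.5 ± 1.92 against 24.3 ± 2.13 RPKM, 1.42 ± 0.14, adjusted p = 0.000272) and Pdgfrb (0.99 ± 0.15) rose, whereas Ptch1 fell by 1.90 ± 0.32. The leukocyte gene Fcer1g rose by 1.42 ± 0.29, but not without SIX2− library 2 (adjusted p = 0.0580), with replicates 1 and 2 only (0.0558) or with a pseudocount of 0.1 (0.0766). Pdgfrb lost its call with replicates 1 and 2 only (0.0551). With only these groups in the fit calls were lost by Pdgfrb (0.0821), Ptch1 (0.0609) and Fcer1g (0.111), and Crabp1 kept its call.

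Of the tests below, those of depth and scaling for matrix genes were set down before results were seen, the others after. The second pattern was that interstitial matrix genes were not higher in Tdt+ cells. Depth is argued against: each matrix gene called lower had at least 113 estimated reads per Tdt+ library. Scaling stays open: the list's median less that of all genes (−0.61 or lower under 4 scalings) cancels shifts common to all. A candidate explanation is that Tdt− cells held another matrix-rich mesenchyme, such as that around the ureter. A list of 6 of its genes, made after the pattern was seen, had a median of −1.03, with Tbx3 (−1.61 ± 0.28, adjusted p = 0.0130) and Tshz3 (−1.46 ± 0.30, adjusted p = 0.0240) called and Bmp4 (−1.09, adjusted p = 0.0558), Tbx18 (−0.96), Myocd (−0.78) and Tbx2 (0.01) not. Tbx3 and Tshz3 were not called without Tdt− library 1 (0.177 and 0.0869) or 2 (0.164 and 0.343), or with no filter (0.0921 and 0.124), nor Tshz3 after quantile normalisation (0.0513). These genes were low, from 2.09 to 32.8 RPKM in Tdt− cells, and 1 of them is in the cortical stromal list, so the explanation stays open.

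The third pattern was that Six3 was high in GFP+ cells (52.3, 41.5 and 38.9 RPKM) and varied among SIX2+ libraries (15.2, 0.232 and 0.0251) and unsorted NZC libraries (12.7, 5.16 and 0). Reads of the paralog Six2 are argued against, since the ratio of Six3 to Six2 differed by a factor of 922 among the SIX2+ libraries. The sorting and library method stays open: the highest Six3 value among these libraries was 65.6 times the next, but that rests on 1 library, and the labels do not say which RNA kit each library had. A candidate explanation is the Six2TGC allele. Six3 was at most 0.00757% of Six2 in the Tdt− libraries and 11.2% to 16.8% in GFP+ libraries. That explanation also needed low Six3 in libraries whose label gives no allele, and this was not met, with 5.05% of Six2 in SIX2+ library 1 and 19.5% and 7.58% in NZC libraries 1 and 2. The labels do not settle which embryos those libraries came from, so the allele stays open and a wrong or missing allele label was not tested.

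For comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05, and the real split gave the most genes in each (1 of 10). These splits took no account of the pairing by number found for SIX2+ with SIX2−, GFP+ with GFP− and SIX2− with unsorted libraries. The real count and the highest other were 3109 and 0 for SIX2+ against SIX2− (limma, 844 at an unadjusted p under 0.05), 4219 and 0 for GFP+ against GFP− (678), 4697 and 1 for SIX2+ against NZC, 1424 and 21 for SIX2− against NZC, and 394 and 0 for SIX2+ against GFP+ (1013).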
